A study of Mus musculus with 6 samples.

How the data were processed

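RNA was measured in 6 libraries of mouse stomach fibroblasts, 3 of cancer-associated fibroblasts (CAF) and 3 of fibroblasts from control stomachs (normal). The mice carried the iLgr5;GLI2A transgenes, a gastric cancer model in which an active GLI2 is switched on in Lgr5-expressing stem cells, and were 8 weeks old. Per the labels' protocols, cancer was induced with tamoxifen by gavage for 5 days and then doxycycline in the chow for 3 weeks, with doxycycline also in the drinking water for the first 3 days, and control mice received corn oil without doxycycline. Cells were dissociated from the stomach with EDTA and collagenase and sorted as live podoplanin-positive cells after removal of CD31-positive endothelial, CD45-positive immune and EpCAM-positive epithelial cells. Each library held the cells of 1 or 2 mice (1, 2 and 2 mice for CAF libraries 1, 2 and 3, and 1, 1 and 2 mice for normal libraries 1, 2 and 3). The libraries thus came from separate mice or pairs of mice. Libraries were made by MARS-seq, a method that counts the 3′ ends of polyadenylated transcripts.

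The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 without versions and the mouse build mm10. Whether molecular identifiers were collapsed, which annotation was counted and whether strand was used are not given in the sources used here. The deposited table holds raw counts per gene symbol, from the authors, and these counts are the values tested here. It also holds a normalized signal, which per the file headers is the normalized count (raw count divided by 1 size factor per library in the values), and a regularized value on the log2 scale, named by the suffix in the headers. The authors' own comparison is deposited beside them as a log2 fold change, a p-value and an adjusted p-value for each gene. All 14228 genes listed had at least 6 counts in some library, so genes below that level were removed before deposit. The normalized signal served only to check the size factors, and the regularized values were not used.

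The total count was 644522, 6422568 and 6421010 in CAF libraries 1 to 3 and 3259644, 903176 and 768420 in normal libraries 1 to 3. A gene with 0 counts over all 3 normal libraries could have a level of up to 0.743 CPM (counts scaled to a common library total, as edgeR defines it), the level of 3 counts over the group, and over all 3 CAF libraries of up to 0.196 CPM. These floors, and the exact binomial intervals given for shares of counts (95%), cover counting error only.

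Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with its defaults, library sizes were scaled by trimmed mean of M-values, and the quasi-likelihood F test (glmQLFit, glmQLFTest) was applied to the group term alone, with Benjamini-Hochberg adjustment over the 10148 genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic and are approximate. CPM values are on the scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on the same fit, with a preset correlation between genes of 0.01, over the lists with at least 3 tested genes. The 50 lists (28 of pathways and fibroblast states and 22 of cell type markers), the tests and the rule for naming genes were fixed before the data were examined. By that rule the text names the 12 genes of smallest p in each direction among called genes with a mean of at least 20 raw counts and no overlap between the groups, up to 4 called members of each list described (or up to 2 of smallest p where none was called), and a fixed set: Hsf1, Inhba and Thbs2, the sort markers Pdpn, Ptprc, Pecam1 and Epcam, and Acta2, Fap, Col1a1, Gli1, Gli2 and Lgr5. Predicted genes without a proper symbol were counted and not named, and 1 gene that the rule takes is not reported here. HSF1, INHBA and THBS2 are known to be the subject of the published study of these samples, so their values are no independent evidence.

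The tests were run on simulated counts with the means, dispersion and library sizes of the real libraries. Among 10148 simulated genes for CAF against normal, 0 of 50 genes changed 2-fold were called, 9 of 50 changed 4-fold, 31 of 50 changed 8-fold and 44 of 50 changed 32-fold, all with the right sign, and 6 unchanged genes were called. Of 20 unchanged lists 0 were called by camera, and of 5 lists raised 2-fold 5 were called; genes were drawn independently there, so this does not test lists whose genes vary together.

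The alternatives listed before the data were examined were DESeq2 1.42.0, limma-voom, size factors by relative log expression, upper-quartile factors, no filter on low counts, a filter of at least 10 counts in 3 libraries, each library left out in turn, the number of mice as a covariate and removal of ribosomal protein genes (mitochondrially encoded genes were not in the table); for lists, an estimated correlation and fry were added. Alternatives chosen after seeing the data were the side of a GC trend as a block, a GC offset per library, omission of normal libraries 1 and 2, removal of gland marker genes and, for the lists, upper-quartile factors, no filter and removal of ribosomal protein genes. GC content was taken over the last 500 nt of the longest GENCODE M21 transcript of each gene, which was found for 10022 of the tested genes (98.8%). Gene positions are those of RefSeq on GRCm38.p6, the assembly of mm10, matched by symbol for 14169 genes and by synonym for 47.

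No pair of libraries agreed within sampling noise. The labels name no batch, date or pairing of mice across the groups. Genes with near-identical copies, such as Hspa1a and Hspa1b, can share reads, so their counts are uncertain, and without a stated strand a gene and its antisense partner cannot be separated.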

Results

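The data were counts of RNA 3′ ends in podoplanin-positive, CD31-, CD45- and EpCAM-negative stomach cells of mice with induced gastric cancer (CAF, n = 3 libraries) and of control mice (normal, n = 3 libraries). The depth ranged from 644522 to 6422568 counts among the CAF libraries and from 768420 to 3259644 among the normal libraries, and 11627 to 14118 genes had a count. The comparison addressed how gene expression in stomach fibroblasts differs between mice with induced cancer and controls. All CAF mice had received tamoxifen and doxycycline and the control mice neither, so effects of the drugs and of the cancer cannot be told apart. The genes of the gastric gland lists (pit and neck, chief, parietal and enteroendocrine cells) took 0.859%, 0.950% and 0.691% of the counts in CAF libraries 1, 2 and 3. In normal libraries 1, 2 and 3 they took 28.5%, 24.6% and 4.77%. The 95% exact binomial intervals were no wider than 24.5% to 24.7% (normal library 2). The fibroblast identity list took 1.44%, 3.52% and 4.56% in the CAF libraries and 0.964%, 1.44% and 4.18% in the normal libraries. Normal libraries 1 and 2 thus held more gland RNA and a lower share of fibroblast RNA than normal library 3. CAF library 1 also had a low fibroblast share (1.44%, as in normal library 2), at a gland share of only 0.859%.

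**Figure D1:**
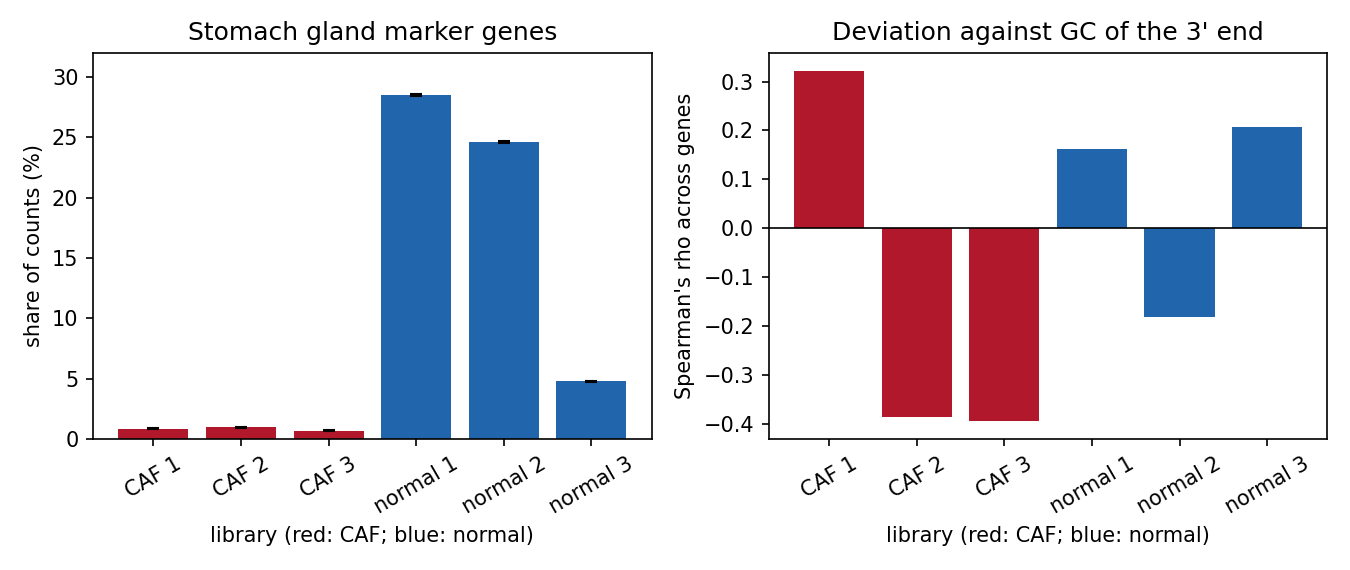
Left, the share of counts (%) from gastric gland marker genes in each library, with 95% exact binomial intervals. The share was below 1% in the 3 CAF libraries and between 4.77% and 28.5% in the normal libraries. Right, Spearman's rho across genes between each library's deviation from the mean of all libraries and the GC content of the transcript 3′ end, which was positive in CAF 1, normal 1 and normal 3 and negative in the other libraries.

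In CAF libraries the lists of matrix proteases, matrix proteins and cytokines and growth factors rose, and those of gastric pit, chief and parietal cells fell by camera with a preset correlation. With an estimated correlation none of them passed (adjusted p = 0.318 for proteases, cytokines and pit, chief and parietal cells, and 0.377 for fibrillar matrix). Igf2, an imprinted growth factor of fetal tissues, was 68.0-fold higher in CAF (2419 ± 529 CPM) than in normal fibroblasts (35.8 ± 7.23 CPM; SD, n = 3 in each group). Il11, a cytokine of the interleukin-6 family, was 47.8-fold higher, and Grem1, a secreted BMP inhibitor, was 39.9-fold higher. Psca, a surface protein of gastric pit and neck cells, was 40.4-fold lower in CAF (165 ± 18.0 CPM against 6689 ± 4706 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 112 of 10148 genes differed between the groups, 91 higher and 21 lower in CAF, and 3 of the 112 are predicted genes that are not named.

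Among the 12 genes of smallest p that were higher in CAF were Napsa, Igf2, Foxe1, Hp, Wif1, Prg4, Chrdl2, Scgb1c1, Cldn3, Cldn6 and B3gnt5. Napsa, an aspartic protease (mm10 chromosome 7, 44572445 to 44586846), rose from 1.80 ± 0.634 to 439 ± 154 CPM, a log2 fold change of 7.93 ± 0.52 (SE; adjusted p = 0.00483 by edgeR). Igf2 (chromosome 7, 142650768 to 142666816) had a log2 fold change of 6.09 ± 0.44 and the same adjusted p. Foxe1, a forkhead transcription factor, rose 115-fold and Hp, the haemoglobin-binding plasma protein haptoglobin, rose 72.0-fold. The secreted Wnt inhibitor Wif1 rose 38.6-fold, and Prg4, the lubricating glycoprotein of joints, rose 24.4-fold. The tight-junction gene Cldn3 rose 20.1-fold and the secretoglobin Scgb1c1 rose 96.0-fold (70.9-fold to 166-fold with 1 library left out). The BMP antagonist Chrdl2, the tight-junction gene Cldn6 and the glycosphingolipid enzyme B3gnt5 had 1, 2 and 1 counts over the normal libraries, and their pooled rate ratios were 526 (95% counting interval 94.2 to 20800), 104 (28.6 to 857) and 141 (25.2 to 5570). With 1 library left out, their fitted folds ranged from 258 to 3120 for Chrdl2, 86.4 to 167 for Cldn6 and 92.2 to 869 for B3gnt5. Adjusted p-values of these genes ranged from 0.00483 to 0.0124. H19, the imprinted non-coding neighbour of Igf2, was chosen after its values were seen. It was 79.7-fold higher in CAF (adjusted p = 0.0183 by edgeR). Igf2os, likewise chosen after its values were seen, was 21.2-fold higher but lies antisense to Igf2, and its reads cannot be told from those of Igf2 without strand.

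The 12 genes of smallest p among those lower in CAF were Mucl3, Mgst3, Psca, Mogat1, Syt8, Osgin1, St6galnac2, Tmed6, Mt4, Gal3st1, Krt1 and Plch2. Mucl3, a mucin-like gene, fell 15.0-fold, from 620 ± 268 to 40.5 ± 18.7 CPM (log2 fold change -3.91 ± 0.51 SE, adjusted p = 0.0216 by edgeR). Mgst3, a microsomal glutathione transferase, fell 6.93-fold, and the sialyltransferase St6galnac2 fell 3.84-fold. Krt1, a keratin of stratified squamous epithelium, fell 355-fold (231-fold to 559-fold with 1 library left out, except normal library 1, without which it was below the filter), and Mt4, a metallothionein of squamous epithelium, fell 299-fold (140-fold to 556-fold). Both were much lower in normal library 3 than in the other normal libraries, at 6.25 CPM for Krt1 and 13.8 CPM for Mt4, against 140 and 133 CPM in normal library 1. Psca was at 1456 CPM in normal library 3 and 10573 CPM in normal library 1. Adjusted p-values of these 12 genes ranged from 0.0216 to 0.0482. With the GC side as a block, a fit chosen after seeing the data, 6 of them did not pass: Mogat1, Krt1, Plch2, Tmed6, Syt8 and Gal3st1 (adjusted p = 0.0592, 0.0592, 0.0608, 0.065, 0.0654 and 0.0776). With the number of mice as a covariate only Mucl3 and Krt1 passed (adjusted p = 0.0473 and 0.0294). Krt1, Mt4 and Psca were 48.8-fold, 55.0-fold and 22.1-fold lower in that fit. With limma-voom Krt1, Mt4 and Tmed6 were 134-fold, 152-fold and 110-fold lower. The median log2 fold change was 4.42 among the 91 genes higher in CAF, or 4.40 with 4 genes at 0 in the normal libraries set to their lower bound, and -3.89 among the 21 lower genes.

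**Figure D2:**
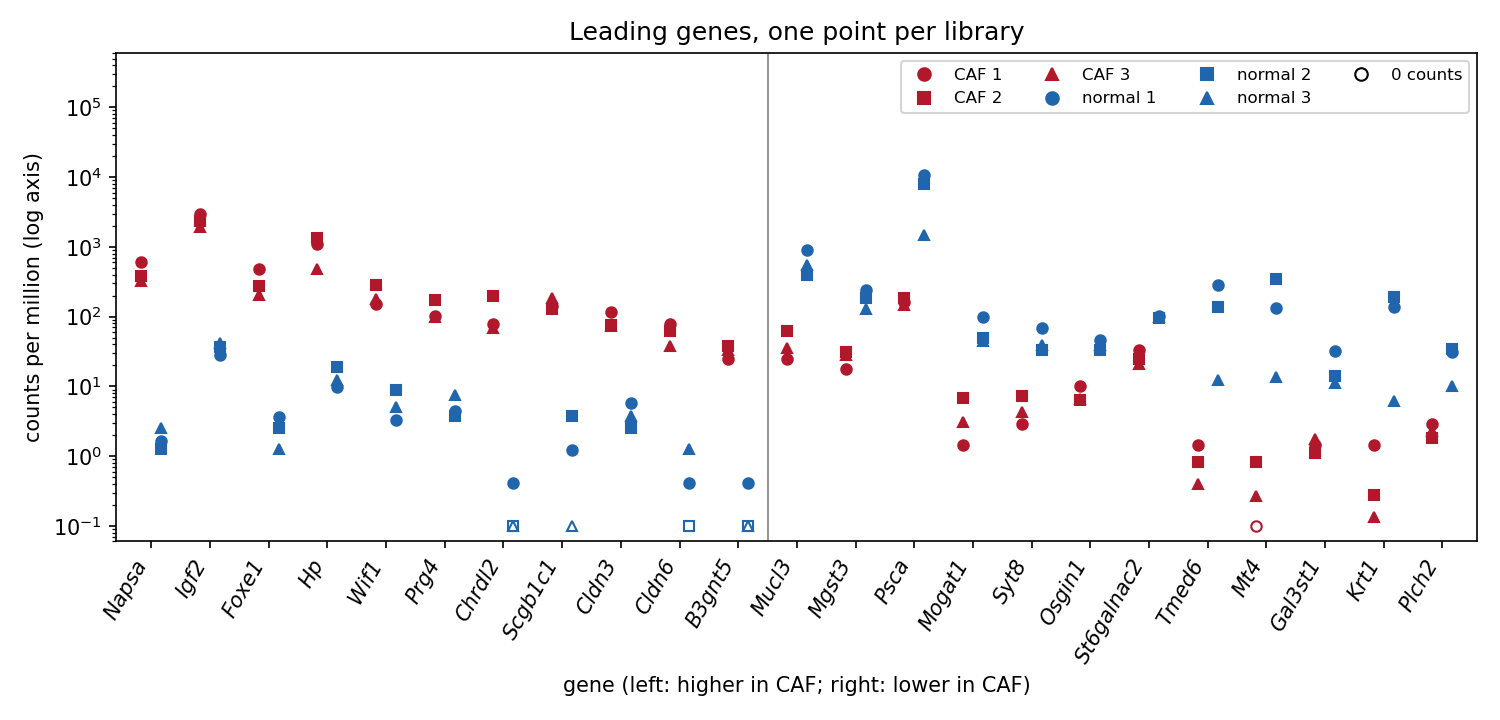
CPM on a log axis for the genes of smallest p named in each direction, with 1 point per library (red, CAF; blue, normal; open symbols at the bottom, 0 counts). The groups do not overlap for any gene shown, and normal 3 lies nearest the CAF libraries for Psca, Tmed6, Mt4 and Krt1.

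Among matrix proteases and their inhibitors, all 21 tested genes had a positive fold change, with a median log2 fold change of 1.56. Adam12, Timp1 and Mmp10 rose over all genes tested, and 9 genes rose when adjusted over the list alone. Adam12, a membrane metalloprotease, was 38.9-fold higher. Timp1, a tissue inhibitor of metalloproteases, was 15.3-fold higher (944 ± 350 against 62.0 ± 43.5 CPM), or 11.8-fold to 23.0-fold with 1 library left out. Mmp10, or stromelysin 2, averaged 467 ± 419 CPM in CAF and 2.11 ± 3.66 CPM in normal fibroblasts, where only normal library 2 had counts, so that its fold is not bounded without that library. Timp1 and Mmp10 did not pass with the number of mice as a covariate (adjusted p = 0.0718 and 0.0983). The list rose by camera (adjusted p = 1.89e-12; adjusted p = 0.318 with an estimated correlation). Fibrillar collagens and matrix had a median of 1.48, with 2 of 31 genes higher over all genes tested and 9 adjusted over the list alone (camera adjusted p = 1.27e-08; adjusted p = 0.377 with an estimated correlation). Its called genes were the fibrillin Fbn2, 6.13-fold higher, and the thrombospondin Thbs4, 6.88-fold higher. Neither passed with the GC side as a block (adjusted p = 0.0501 for each) or the number of mice as a covariate (0.067 and 0.0562). The basement membrane list had 1 of 15 genes called, Nid2 (nidogen 2), which was 10.9-fold higher, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00335; adjusted p = 0.478 with an estimated correlation). The gland share was higher in all 3 normal libraries, and with normal libraries 1 and 2 left out the camera test gave 2.7e-05 for proteases, 0.0479 for fibrillar matrix and 0.957, with the direction turned, for basement membrane.

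Cytokines and growth factors rose as a list, with a median of 1.41 over 22 genes, 2 called (Igf2 and Il11) and 7 adjusted over the list alone (camera adjusted p = 7.8e-07; adjusted p = 0.318 with an estimated correlation). Without normal libraries 1 and 2, in which the gland share was highest, this list had an adjusted p of 0.000211 by camera. The chemokine list had a median of 0.88 with 0 of 14 genes called and 3 higher adjusted over the list alone (camera adjusted p = 0.00924; adjusted p = 0.318 with an estimated correlation). Its genes of smallest p did not pass: Ccl7 had a log2 fold change of 1.57 (adjusted p = 0.0638 by edgeR) and Cxcl5 of 5.84 (adjusted p = 0.1), or 5.40 to 6.86 in the 4 fits without 1 library in which it passed the filter. The TGF-beta and activin list had a median of 1.13 with 0 of 18 genes called and 5 adjusted over the list alone (camera adjusted p = 4.28e-05; adjusted p = 0.318 with an estimated correlation). Inhba, the activin A subunit, was at 34.5 ± 25.7 CPM in CAF and had 0 counts in all 3 normal libraries, at least 46.5-fold higher against 3 counts over the group (18.3-fold to 58.9-fold with 1 library left out), but did not pass (adjusted p = 0.0521 by edgeR). Inhbb, another activin subunit, was 6.87-fold higher (5.54-fold to 12.7-fold with 1 library left out; adjusted p = 0.0692). Both medians of lists that hold Inhba were the same with Inhba at its bound.

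The CAF state lists also rose by camera. Myofibroblast CAF markers had a median of 1.32, with 0 of 16 genes called and 7 adjusted over the list alone (camera adjusted p = 5.64e-06; adjusted p = 0.318 with an estimated correlation). Thy1 was its member of smallest p after Inhba, 6.13-fold higher with an adjusted p of 0.0564 by edgeR. Inflammatory CAF markers had a median of 1.22 over 19 genes, with Hp and Saa3 called and 3 adjusted over the list alone (camera adjusted p = 0.000266; adjusted p = 0.318 with an estimated correlation). Saa3, an acute-phase serum amyloid, was 48.5-fold higher (776 ± 468 against 16.5 ± 17.2 CPM), or 36.6-fold to 104-fold with 1 library left out. It did not pass with the number of mice as a covariate (adjusted p = 0.0858). Saa3 was also the called gene among 9 antigen-presenting CAF markers, whose median was 0.79, with 1 adjusted over the list alone (camera adjusted p = 0.00346; adjusted p = 0.318 with an estimated correlation). Saa3 is an acute-phase gene and not an antigen-presentation gene. The fibroblast identity list had a median of 1.10 with 0 of 16 genes called and 2 adjusted over the list alone (camera adjusted p = 0.00335; adjusted p = 0.563 with an estimated correlation). Its direction by camera turned without normal libraries 1 and 2 (adjusted p = 0.959). Markers of adventitial fibroblasts had a median of 0.05 over 15 genes with 0 called and 1 adjusted over the list alone (camera adjusted p = 0.624), and those of telocytes and subepithelial fibroblasts a median of 0.02 over 13 genes with 0 called (camera adjusted p = 0.962).

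Among signalling lists, Wnt genes had a median of 0.48 over 19 genes with 1 called, Wif1, and 3 higher adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.419 with an estimated correlation). Wif1 is a Wnt inhibitor. The BMP list did not pass (median 0.41 over 16 genes, camera adjusted p = 0.505), with Grem1 called and 4 higher and 3 lower adjusted over the list alone. Targets of YAP and SRF had a median of 0.72 over 16 genes with 0 called and 2 adjusted over the list alone (camera adjusted p = 0.00517; adjusted p = 0.318 with an estimated correlation). The Hedgehog list had a median of 0.67 over 14 genes with 0 called and 2 adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.563 with an estimated correlation), and its direction by camera turned without normal libraries 1 and 2 (adjusted p = 0.64). Ptch1, the Hedgehog receptor and target, was 3.25-fold higher without passing (adjusted p = 0.0617 by edgeR). Gli1 was at 92.1 ± 34.3 CPM in CAF and 102 ± 95.5 CPM in normal fibroblasts (adjusted p = 0.95), Gli2 at 10.4 ± 3.12 and 11.9 ± 8.11 CPM (adjusted p = 0.912) and Lgr5 at 6.0 ± 3.99 and 4.04 ± 4.48 CPM (adjusted p = 0.776).

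The heat shock response list did not pass (median -0.18 over 22 genes, 0 called, 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0741). Hsf1, the heat shock transcription factor, was at 49.3 ± 6.81 CPM in CAF and 71.6 ± 16.5 CPM in normal fibroblasts, a log2 fold change of -0.55 ± 0.31 (SE; adjusted p = 0.477 by edgeR). The inducible chaperones Hspa1a and Hspa1b, which share nearly identical sequence and can exchange reads, were at log2 fold changes of -1.54 and -1.57 without passing (adjusted p = 0.0705 and 0.11). Thbs2 was 3.02-fold higher, at 20.7 ± 6.19 against 6.93 ± 6.0 CPM, and did not pass (adjusted p = 0.289). It ranged from 2.36-fold to 5.0-fold with 1 library left out and passed without normal library 3 (adjusted p = 0.0427). The list of extracellular vesicle biogenesis and release did not pass either (median 0.14 over 20 genes, 0 called, camera adjusted p = 0.725). The interferon-stimulated list fell by camera, with a median of -0.66 over 18 genes, 0 called and 2 lower adjusted over the list alone (adjusted p = 0.00874; adjusted p = 0.478 with an estimated correlation). Ifi27 and Isg15 had log2 fold changes of -2.02 and -1.80 without passing (adjusted p = 0.0762 and 0.0906 by edgeR). Immediate early genes fell by camera with a median of -0.51 over 23 genes and 0 called (adjusted p = 0.0317; adjusted p = 0.318 with an estimated correlation). The lists of cell cycle, hypoxia and glycolysis, endoplasmic reticulum stress, cholesterol biosynthesis, oxidative stress, complement and ribosomal protein genes did not pass by camera, with adjusted p-values of 0.288, 0.0752, 0.744, 0.0741, 0.787, 0.201 and 0.694, and none of their genes was called.

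Gastric pit and neck cell markers fell in CAF with a median of -3.32 over 12 genes, of which 2 were called, Mucl3 and Psca, and 11 adjusted over the list alone (camera adjusted p = 3.67e-14; adjusted p = 0.318 with an estimated correlation). Chief, parietal and enteroendocrine cell markers had medians of -6.29, -4.80 and -4.82 over 5 genes each, with 0 called and 5, 5 and 4 lower adjusted over the list alone (camera adjusted p = 2.41e-07, 1.68e-06 and 0.00169; adjusted p = 0.318, 0.318 and 0.43 with an estimated correlation). Pgc, the chief cell zymogen progastricsin, averaged 88194 ± 74200 CPM in normal and 2022 ± 1181 CPM in CAF libraries (adjusted p = 0.0666 by edgeR). Squamous forestomach markers had a median of -1.76 over 8 genes with 0 called and 3 lower adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.563 with an estimated correlation), and turned direction without normal libraries 1 and 2 (adjusted p = 0.526). The general epithelial list did not pass (median -1.03 over 13 genes, camera adjusted p = 0.725), with Cldn3 called higher and 2 higher and 4 lower adjusted over the list alone. Against normal library 3 alone the median of the general epithelial list was 1.27, and the list passed by camera in 2 of 18 alternatives. Among 6 intestinal-type and metaplasia genes, which did not pass as a list (camera adjusted p = 0.511), the antimicrobial lectin Reg3g was 23.5-fold higher in CAF (adjusted p = 0.038 by edgeR), without passing with the GC side as a block (adjusted p = 0.0501) or the number of mice as a covariate (0.0858).

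The sorted and excluded markers were looked up in every library. Ptprc had 0 counts in CAF library 1 and normal libraries 1 and 3, and Pecam1 in CAF library 1 and normal library 3. Pdpn, which encodes podoplanin, was at 89.2 ± 53.2 CPM in CAF and 19.6 ± 14.3 CPM in normal fibroblasts (adjusted p = 0.202 by edgeR). Epcam was present at 158 ± 65.1 and 80.7 ± 68.0 CPM (adjusted p = 0.623). Pecam1, which encodes CD31, was at 2.64 ± 2.30 and 6.08 ± 5.27 CPM (adjusted p = 0.72), and Ptprc, which encodes CD45, at 2.29 ± 2.88 and 1.27 ± 2.19 CPM was below the filter and not tested. Col1a1 was 4.06-fold higher (adjusted p = 0.178), Fap 5.29-fold higher (adjusted p = 0.396) and Acta2 1.87-fold higher (adjusted p = 0.561) in CAF, and none of the 3 passed. With 1 library left out Acta2 was 1.21-fold to 2.54-fold higher, and the ratio of mean CPM for Fap, 4.49 over all libraries, ranged from 2.14 to 19.3. The general leukocyte list rose by camera with a median of 1.27 over 8 genes and 0 called, 1 adjusted over the list alone (adjusted p = 0.0328; adjusted p = 0.563 with an estimated correlation), while macrophage and neutrophil lists did not pass (adjusted p = 0.817 and 0.228). Pericyte markers rose by camera (median 1.24 over 8 genes, 0 called, 2 adjusted over the list alone, adjusted p = 0.00517; adjusted p = 0.318 with an estimated correlation). Blood endothelium, smooth muscle, mesothelium, glia, interstitial cells of Cajal and adipocytes did not pass as lists (camera adjusted p = 0.624, 0.624, 0.228, 0.228, 0.062 and 0.162). Among their genes Myh11, the smooth muscle myosin heavy chain, was 4.55-fold lower in CAF and the glial calcium-binding gene S100b was 33.9-fold higher (adjusted p = 0.0486 and 0.0247 by edgeR). Myh11 did not pass with the GC side as a block (adjusted p = 0.0662) or the number of mice as a covariate (0.0858), and S100b ranged from 21-fold to 47.5-fold with 1 library left out.

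**Figure D3:**
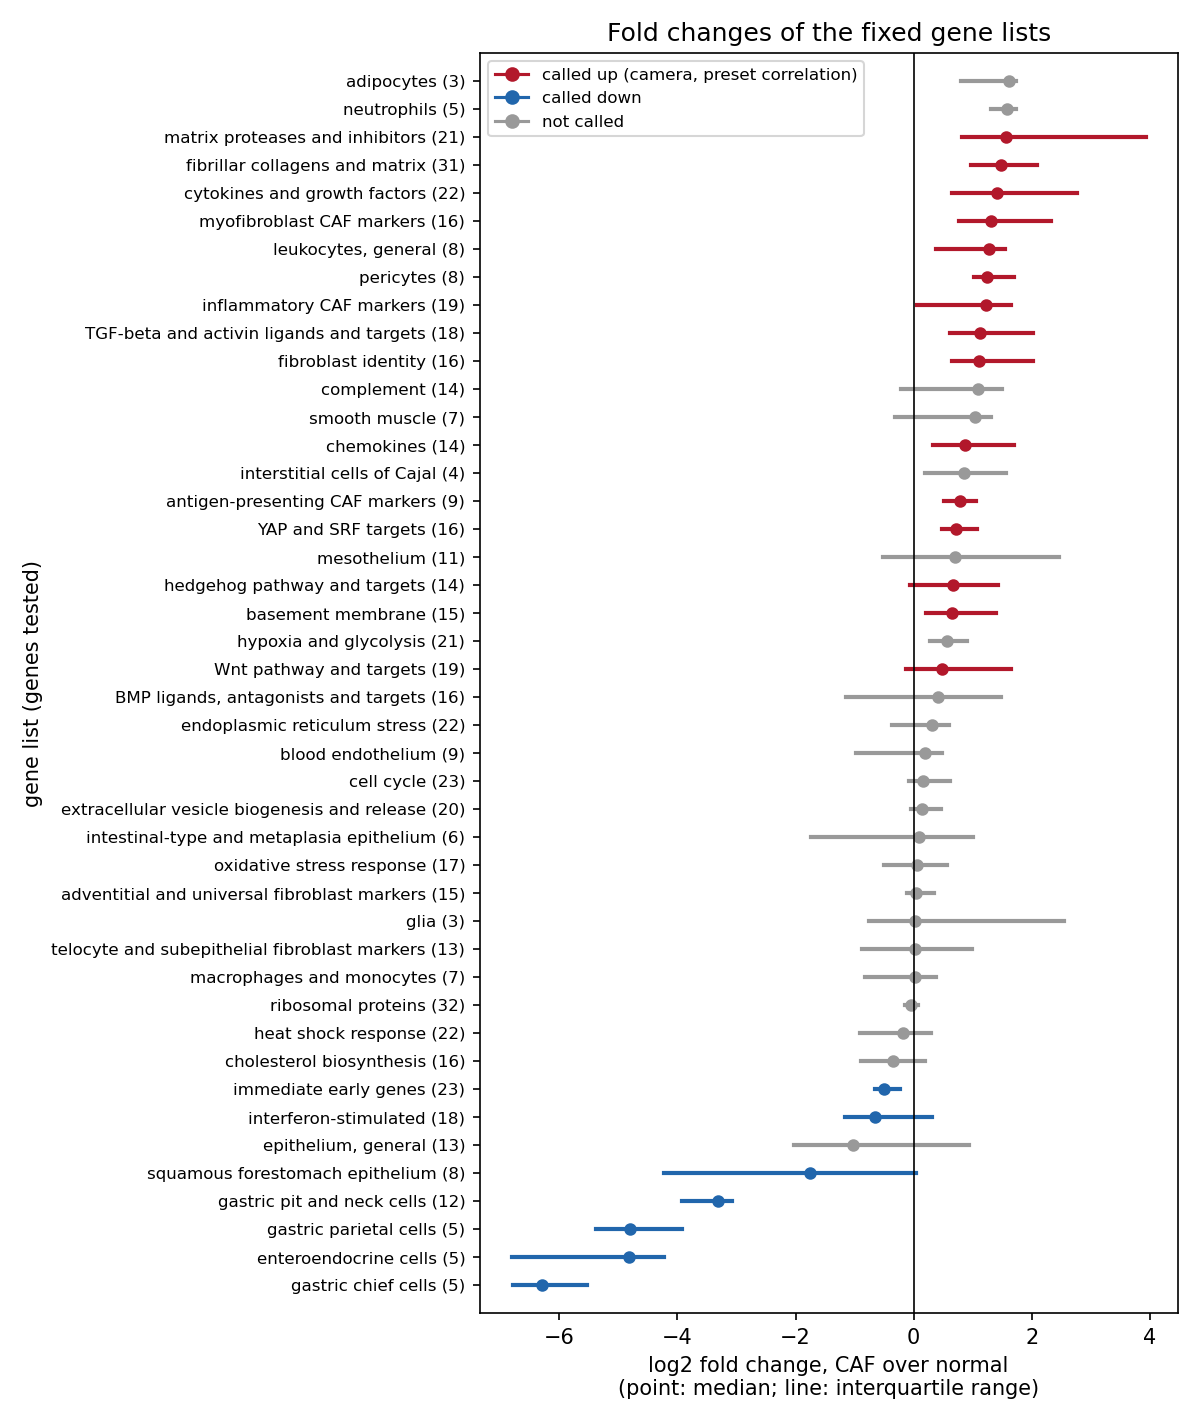
Median (point) and interquartile range (line) of the log2 fold change, CAF over normal, for each list with at least 3 tested genes. The number of tested genes is in parentheses, and lists with fewer are not shown. The 15 lists called up and 7 called down by camera with a preset correlation are coloured, and the gastric epithelial lists lie farthest from 0, with medians of -3.32 to -6.29.

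In all, 22 of the 44 lists tested passed by camera with the preset correlation, and 0 passed with an estimated correlation or by fry's one-direction test, while fry's mixed test, which asks for change in either direction, called 26. The remaining 6 lists had fewer than 3 tested genes. For the lists of endoplasmic reticulum stress, oxidative stress, telocyte and macrophage genes the median was positive and the direction of the test was down, and none of the 4 passed. Over 18 alternatives the call held in 7 for the Hedgehog list, 9 for immediate early genes, 11 each for squamous and leukocyte markers and 13 for chemokines. With the side of the GC trend as a block (chosen after seeing the data) the immediate early and leukocyte lists did not pass (camera adjusted p = 0.105 and 0.115). Without normal libraries 1 and 2, the 2 with the highest gland share, the lists of inflammatory CAF markers, Wnt, TGF-beta and activin, YAP and SRF, chemokine, pericyte and immediate early genes did not pass either (camera adjusted p = 0.242, 0.591, 0.188, 0.194, 0.328, 0.45 and 0.0591), nor did parietal and enteroendocrine markers (0.0536 and 0.328), while myofibroblast and antigen-presenting CAF markers, pit and chief cell markers and interferon-stimulated genes did (0.0193, 0.00429, 5.21e-07, 0.000132 and 0.000132). That fit set the 3 CAF libraries against 1 shallow normal library, normal library 3, in which genes with 0 counts have no bounded fold. In it the median log2 fold change was 1.06 for cell cycle, 1.33 for hypoxia and glycolysis, 3.39 for neutrophils and 2.59 for interstitial cells of Cajal. Telocyte markers were at -0.07, and lymphatic endothelium, with 5 genes tested there and 2 in the main fit, at 7.29. None of these lists passed in the main fit, where lymphatic endothelium was not tested as a list. Over the 18 alternatives the hypoxia and interstitial cell lists passed in 6 each, neutrophils in 3, cell cycle in 2 and telocyte markers in 1. The CAF and normal libraries did not overlap for any of the 112 called genes and for 19.9% of all tested genes, against 10% by chance. The authors' deposited table has 906 genes with an adjusted p-value below 0.05, 392 higher and 514 lower in CAF, and all 112 genes called here were among them with the same sign. In the authors' deposited table Inhba and Col1a1 passed (adjusted p = 6.06e-06 and 0.0412) and Thbs2 did not (adjusted p = 0.196).

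The number of called genes depended on single libraries: it was 49, 4 and 29 without CAF library 1, 2 and 3, and 0, 6 and 1193 without normal library 1, 2 and 3 (edgeR; without normal library 1, 793 genes had an unadjusted p below 0.05), and it was 0 with normal libraries 1 and 2 both left out, where 1271 genes had an unadjusted p below 0.05 (DESeq2, run on all libraries, called 935). The median log2 fold change of the 91 higher genes was 4.13 to 4.59 with 1 library left out. With normal libraries 1 and 2 left out it was 4.39 (median SE 0.924, against 0.56 in the main fit). Higher genes with 0 counts in normal library 3, such as Reg3g, have no bounded fold there, so 4.39 does not show an unchanged size. The median of the 21 lower genes was -3.12 to -4.07 and -2.85 (SE 0.609, against 0.61). All these genes were picked on the same libraries, so their medians hardly show how far folds shrink elsewhere. In genes picked without a CAF and a normal library, the median in that pair ranged from -0.15 to 4.26 over 9 pairs. It was 2.27, 2.63 and 2.12 for CAF libraries 1, 2 and 3 against normal library 3. Without normal libraries 1 and 2, Psca was 8.46-fold and Mt4 24.4-fold lower. There Timp1, Saa3, S100b, Nid2 and Thbs4 were 8.86-fold, 22.0-fold, 18.4-fold, 6.88-fold and 4.2-fold higher, less than in the main fit. Foxe1 and H19 were 258-fold and 155-fold higher, more than in the main fit. Foxe1 was at only 1.25 CPM in normal library 3, below the 3.75 CPM that 0 counts allow there, so a larger fold for Foxe1 is not shown. The libraries also parted by the GC content of transcript 3′ ends across the groups, and with that side as a block 110 genes were called, 96 higher and 14 lower, of which 80 were among the 112. The block kept 73 of the 91 higher and 7 of the 21 lower genes, and the others had adjusted p-values of 0.0501 to 0.0776.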

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

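No paired analysis was possible because the replicate numbers of the CAF libraries follow accession order alone and the labels pair no mouse or library across the groups. The GC block, the GC offset, the omission of normal libraries 1 and 2, the removal of gland genes and the rescaling to fibroblast identity genes were chosen after seeing the data. Size factors by relative log expression, upper-quartile factors, removal of ribosomal protein or gland marker genes and the GC block left every count within 1.5 times the main one, though the block kept only 80 of the 112 calls. Mice as a covariate called 78 genes (70 higher) and kept 56. DESeq2 called 935 genes (400 higher, 535 lower), including all 112, and limma-voom 65 (49 higher), of which 54 were among the 112; the cause was not tested. The number lower in CAF was 40 without a filter, 12 with the stricter filter, 8 with mice as a covariate and 39 with the GC offset; 583 genes were called (101 higher, 482 lower) with libraries rescaled to fibroblast identity genes, themselves higher in CAF; fewer or more genes entered the filtered fits, and otherwise the cause was not tested. Leaving out 1 library gave 0 to 1193 called genes, 0 to 412 higher and 0 to 781 lower, from fewer samples. With normal libraries 1 and 2 left out, only normal library 3 stood against the CAF libraries and was assumed to vary like them. The median log2 fold change there was 0.29 against 0.06 over all genes. It was 4.39 against 4.42 over the higher and -2.85 against -3.89 over the lower genes. Higher genes with 0 counts in normal library 3 have no bounded fold in that fit, so 4.39 does not show an unchanged size. Camera called 18 to 24 lists without 1 library and 16 without normal libraries 1 and 2, but 0 with an estimated correlation and 0 by fry.

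Reversals of direction in named genes concerned genes that did not pass in either setting. Gli1 was at a log2 fold change of 0.21 with limma-voom, 0.02 without CAF library 3, 0.86 without normal library 3 and 0.47 with the GC block, and Gli2 at 0.04 without CAF library 2, 0.18 without normal library 3 and 0.39 with the block, where Lgr5 was at -0.20. Without 1 library each, these ranged from -0.55 to 0.86 and from -0.63 to 0.18, C1qa from -2.03 to 0.14, Camp from -0.47 to 3.29 and S100a8 from -0.23 to 4.12. Without normal libraries 1 and 2, Cfi was at 1.39, C1qa at 1.23 and, with 0 counts in normal library 3 so that the fitted value is no measure of size, Kit at 7.74 and Pecam1 at 6.75, and the lists of fibroblast identity (adjusted p = 0.959), basement membrane (0.957), the Hedgehog pathway (0.64) and squamous forestomach epithelium (0.526) turned; the cause was not tested. For these lists it was the direction by camera that turned. The median log2 fold change in that fit stayed positive for fibroblast identity (0.58), basement membrane (0.21) and the Hedgehog pathway (0.06). Only the median of squamous forestomach epithelium changed sign, from -1.76 in the main fit to 1.09. Depth limits genes near the floor: in CAF library 1, 0 counts allow up to 4.39 CPM. In the simulation of this comparison 0 of 50 genes changed 2-fold were called, so changes of that size were not detectable at this depth and number of libraries.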

Other observations

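The tests of splits and explanations in this part were chosen after the results were seen. Several genes outside the naming rule stood out and were chosen after their values were seen. The thyroid hormone deiodinases Dio2 and Dio3, which activate and inactivate thyroid hormone, were both higher in CAF (22.8-fold and 20.8-fold; adjusted p = 0.0183 and 0.0201 by edgeR). The secreted Wnt inhibitor Sfrp5 was 23.4-fold higher (13.7-fold to 28.5-fold with 1 library left out). Rgs8, Epha8, Klhl6 and Kcns1 had 0 counts in the 3 normal libraries and were at least 126-fold, 87.7-fold, 21.4-fold and 19.9-fold higher in CAF. Without normal library 1 these limits fell to 49.7-fold, 34.5-fold, 8.41-fold and 7.84-fold, and Klhl6 and Kcns1 did not pass with the GC side as a block (adjusted p = 0.0701 and 0.0634) or the number of mice as a covariate (0.106 and 0.0939). Dcpp3 was 112-fold higher (78.2-fold to 251-fold with 1 library left out), with 621 ± 179 CPM in CAF, but did not pass with the number of mice as a covariate (adjusted p = 0.052), and it is a close paralog of Dcpp1 and their reads can be exchanged. Neutrophil markers took 0.231% of the counts in CAF library 2 and 0.0736% in normal library 2, against 0.0113% to 0.0515% in the other libraries.

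The 3 against 3 design gives only 10 splits of the libraries, too few for a share under 0.05. The real split called 112 genes and the highest other split 98, so 1 split of 10 gave as many. It called 22 lists by camera with the preset correlation and the highest other split also 22, so 2 of the 10 splits gave as many. That other split set CAF library 1 and normal libraries 1 and 2 against the rest.

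The split that called 98 genes set CAF library 1 and normal libraries 1 and 3 against CAF libraries 2 and 3 and normal library 2. Depth is argued against, because CAF library 1 was far shallower than CAF libraries 2 and 3 while normal library 1, on the same side as CAF library 1, was deeper than normal library 2 by 1.85 on the log2 scale, and pool size because 2 libraries break a division by the number of mice. The sides of this split are those of the GC trend, set by the sign of each library's correlation with the GC content of the transcript 3′ end. Across genes, the log2 difference between the sides correlated with that GC content (Spearman's rho 0.508 across genes, which are not independent replicates). The medians went from -0.94 in the fifth of lowest GC to 0.46 in the highest. A positive correlation was built in by the way the sides were set, so it is no independent support. Every other split that mixed the groups called 0 genes. A candidate explanation is a difference in library preparation or amplification that acts on GC content. The labels give no batch, and no biological explanation was tested.

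The 21 genes lower in CAF may reflect RNA of gland or surface epithelium in the normal libraries, in spite of the EpCAM gate. Their median log2 ratio of normal library 3 to normal library 1 was -1.0 (quartiles -1.86 and -0.38), below the lower quartile of all tested genes (-0.777). Gland markers were at -4.12, pit and neck markers among them at -2.68, and fibroblast identity genes at 1.56. The 21 genes had a median log2 fold change of -3.89 (median SE 0.61) before and -3.84 (0.646) with the GC side as a block. This cannot decide on the GC trend, since the sides cross the groups and genes that followed the side alone would not have been called. Only 7 of the 21 stayed called. In the 14 lost the median went from -3.81 to -3.78 while the SE rose in 13, and the fit adjusted over more genes. Myh11, one of the 21, is a smooth muscle gene and not an epithelial one. A loss of these transcripts from the stomach in the cancer model stays open and untested. It could come by way of the cancer or of the drugs that induced it, which cannot be told apart here.

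The 91 genes higher in CAF had a median log2 fold change of 4.42 (median SE 0.56) before and 4.45 (0.519) with the GC side as a block. For the same reason this cannot decide on the GC trend as their cause. With the block 18 were no longer called (median 3.19 before and 3.0 after, SE 0.543 and 0.526). Dilution of fibroblast RNA by gland RNA in the normal libraries is argued against as the whole cause of the 91 higher genes. With each library rescaled to its fibroblast identity genes, 55 of the 91 were still called and the median of the 91 was 3.51 (SE 1.0). In all 583 genes were called there, 101 higher and 482 lower. The rescaling lowers CAF as a group, though not CAF library 1 against normal library 3. However, 36 calls ended (median 2.94 before and 2.02 after, SE 0.407 and 0.912). Only 37 genes passed a test against the fibroblast identity median of 1.10 and 4 against its upper quartile (2.02). Genes were also picked without a CAF and a normal library and read in that pair. Their median lay above the fibroblast upper quartile of the same pair in only 7 of 9 pairs, so dilution in part stays open. A higher share of fibroblast RNA stays open for the protease and matrix lists, as adventitial markers had a median of 0.047, below the lower quartile for proteases (0.82), and fibroblast identity genes lay above it. Epithelial tumour cells that escaped the gate could carry some of these genes, such as Cldn3 and Cldn6. Over all 91 genes the median log2 ratio of CAF library 1 to the other CAF libraries, adjusted for GC, was 0.28 (quartiles -0.20 and 0.82). Among genes named above, Grem1, Foxe1 and H19 were at 2.32, 1.33 and 0.84. Il11, Napsa, Igf2, Wif1 and Hp were at 0.50, 0.39, 0.33, 0.17 and -0.14. Cldn3 and Cldn6 were at -0.05 and 0.43. The median of 0.28 lay above fibroblast identity genes (upper quartile -0.12) and below the general epithelial list (median 0.83). All tested genes also lay above the fibroblast value (-0.05), so the test decides nothing and both sources cannot be told apart. Against normal library 3 alone the general epithelial list had a median log2 fold change of 1.27, and against all normal libraries of -1.03. A change in the fibroblasts themselves, through the cancer or the drugs that induced it, remains a hypothesis.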
